A study of Mus musculus with 2 samples.

How the data were processed

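Gene expression was measured in 2 cultures labelled as primary mouse hepatic stellate cells, the liver cells that make scar matrix when activated. Per the labels, 1 culture received a control adenovirus (Ad_NC) and the other an adenovirus for AGGF1, an angiogenic factor with G-patch and FHA domains (Ad_AGGF1). Both viruses were used at a multiplicity of infection of 50, and RNA was taken on day 8. There was 1 library per group. The study's description names digital tag profiling as the assay, and the labels name Illumina library protocols. The submitters' processing notes name Bowtie 0.12.2 and the mouse genome build mm8. The counting tool, the annotation release and any filters are not given in the sources used here.

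The authors deposited a table of whole read counts for 41128 Ensembl genes, with no normalisation per the file headers and the values. Its totals were 9960107 reads for Ad_NC and 9907944 reads for Ad_AGGF1. Empty extra cells on 16 lines of it were ignored. A second deposited table holds RPKM (reads scaled to gene length and depth) for the same genes. Dividing counts by the authors' RPKM gave a whole gene length for 100% of the 18916 genes with a read, within a relative tolerance of 1e-06, so these values use the summed gene counts as depth. If reads were short tags from 1 site per transcript, dividing by gene length lowers long genes, but a ratio between both libraries at 1 gene does not depend on length.

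The authors' deposited comparison table holds a scaled count per library (a normalised signal), a log2 fold change, a p-value and a q-value per gene. Their test and scaling are not given in the sources used here. For genes with nonzero entries the deposited scaled counts equalled the TMM-normalised CPM values computed here, with a largest relative deviation of 5.11e-15. Scaled counts below 1 were entered as 0, which applied to 5066 genes with at least 1 read in Ad_NC and 5296 in Ad_AGGF1. The deposited p-values followed the scaled counts, which sum to 997797 in Ad_NC and 999266 in Ad_AGGF1, and not the reads. Over 178 genes the ratio of the deposited −log10 p-value to that of an exact binomial test had a median of 1.02 with scaled counts and 0.116 with unscaled counts.

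All levels and ratios reported here start from the deposited counts. They were normalised with TMM in edgeR 4.0.16 under R 4.3.3, which gave effective library sizes of 9967860 and 9900238. Levels are in CPM, counts scaled to the effective library size, and ratios are log2 of Ad_AGGF1 over Ad_NC. Further steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. Gene symbols were matched by Ensembl identifier to a reference table. It held 40254 of the 41128 identifiers, and the other 874 carried 0.0841% of the reads in Ad_NC and 0.0927% in Ad_AGGF1. The reference at hand was of another build than mm8, so no coordinates are given.

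With 1 library per group there is no replicate check, and no p-value is given for a difference of any gene or list between them. The exact binomial test above served only to compare with the deposited p-values. Each ratio carries a 95% interval for counting error, from exact Clopper-Pearson bounds on the share of a gene's reads that fell in Ad_AGGF1. Shares of a library's reads carry exact Clopper-Pearson intervals. These intervals and the floor of 3 reads (0.301 CPM in Ad_NC and 0.303 CPM in Ad_AGGF1) cover counting error only, since reads without molecular identifiers are not independent molecules and cultures of 1 group can differ. A gene with at least 20 reads over both libraries was called measured, which left 12120 genes with 99.8% of the reads in each library. The size criterion for a higher or lower gene was a ratio of at least 2-fold with an interval that excludes a ratio of 1.

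Before the data were examined, 34 gene lists were fixed, 4 of them primary (stellate cell activation markers, collagens, TGF-beta/SMAD target genes and quiescent stellate cell markers). For each list the median log2 ratio of its measured members was taken. Its percentile was found among 10000 random lists of the same size, matched on mean expression in 20 bins. Random genes were drawn independently, so a percentile ignores correlation between the members of a list. Some lists share members, and their percentiles are not separate evidence. A median's 95% interval came from 2000 binomial resamplings of each member's reads. The rule for named genes was also fixed. It took Aggf1 and every member of a primary list that met the size criterion. From each other list it took at most 4 such members with the largest ratios, or the 2 most abundant where none met it. It added the 15 higher and the 15 lower genes whose intervals lay farthest from a ratio of 1, leaving out predicted genes and clone names. Not every gene that the rule selects is reported here. Genes named outside it are marked as chosen after their values were seen.

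The calculation was tested on simulated data, with Poisson counts for the real genes and 200 genes changed by known folds in a comparison of Ad_AGGF1 against Ad_NC. The criterion ran on the 12131 simulated genes that passed the read minimum. Of the 50 genes changed by each fold, those below the minimum included, it recovered 2% at 1.5-fold, 46% at 2-fold, 100% at 3-fold and 96% at 5-fold, where 50, 49, 50 and 49 passed the minimum. It called 36 of 11933 unchanged genes. Apart from the changed genes, both simulated libraries shared the same mean levels, with Poisson noise alone. These rates therefore cover read sampling and not differences between cultures. Alternatives planned before the data were examined were total-count scaling, median-of-ratios factors from DESeq2 1.42.0, other read minimums and fold sizes, no interval, and the authors' RPKM with pseudocounts of 1 or 0.1, for genes with a mean of at least 1 RPKM or without that filter. A correction for gene length by a local regression (lowess, fraction 0.3) was added after seeing the data. Members of gene families with near-identical copies, such as histone, lysozyme, Gstt and tryptase genes, can share reads, and their single values are uncertain.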

Results

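The data comprised 2 libraries labelled as primary mouse hepatic stellate cells, 1 labelled as given a control adenovirus (Ad_NC) and 1 an AGGF1 adenovirus (Ad_AGGF1), both collected on day 8. The libraries held 9960107 and 9907944 reads counted to genes. Reads were seen for 17236 genes in Ad_NC and 17430 in Ad_AGGF1, and the 10 most abundant genes took 12.7% and 12.5% of the reads. The comparison asks which transcripts differ when AGGF1 is supplied to stellate cells in culture, where these cells activate. There are no replicates, so each difference below is between these 2 libraries, and each interval covers counting error alone. A gene counted as at least 2-fold higher or lower also has a 95% interval that excludes a ratio of 1, and at least 20 reads over both libraries.

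Aggf1 itself (ENSMUSG00000021681), the targeted gene, did not differ at this depth. It had 653 reads in Ad_NC (65.5 CPM) and 668 in Ad_AGGF1 (67.5 CPM), a log2 ratio of 0.04 with a 95% interval of −0.12 to 0.20. The upper bound corresponds to 1.15-fold. In the authors' deposited table the log2 fold change of Aggf1 was also 0.04. The counts of this gene thus do not check the labels, and the species and extent of the insert are not given in the sources used here. Directions below refer to the library labelled Ad_AGGF1 against the library labelled Ad_NC.

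Transcripts of macrophages, the phagocytes that in liver include Kupffer cells, were the most abundant cell type markers in both libraries. The 22 macrophage genes took 4.47% of the reads in Ad_NC (4.46 to 4.49%) and 3.97% in Ad_AGGF1 (3.96 to 3.98%). The 20 stellate activation genes took 0.298% (0.294 to 0.301%) and 0.281% (0.278 to 0.285%), and the 18 endothelial genes 0.206% (0.204 to 0.209%) and 0.141% (0.138 to 0.143%). The median level in Ad_NC was 655 CPM for macrophage genes, 76.9 CPM for endothelial genes and 8.03 CPM for activation genes. Col1a1, the main chain of type I collagen, was at 6.42 CPM in Ad_NC and 2.22 CPM in Ad_AGGF1, and Acta2, smooth muscle actin, at 9.63 and 4.24 CPM. By comparison the lysozyme gene Lyz2 was at 18934 and 17744 CPM and Adgre1, which encodes F4/80, at 5786 and 4414 CPM, both named after their values were seen. No read fell on Gfap or Cnn1, also named after their values were seen, in either library, which allows up to 0.301 CPM in Ad_NC and 0.303 CPM in Ad_AGGF1.

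**Figure D1:**
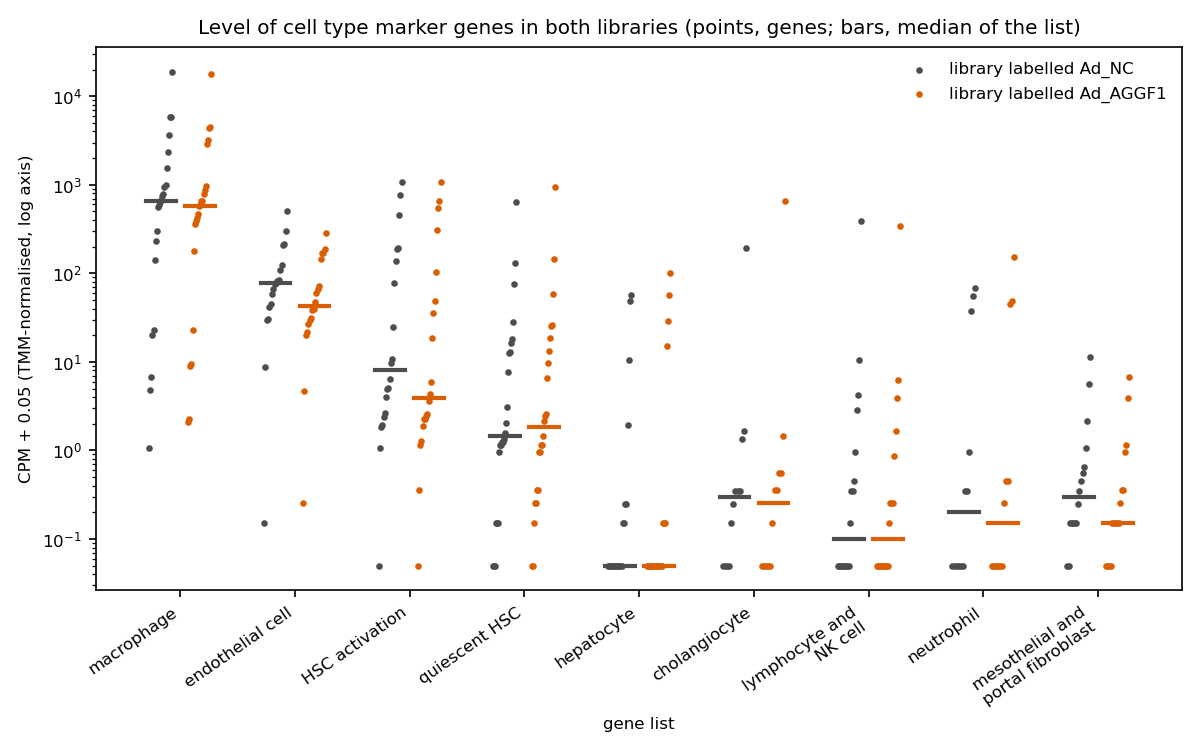
Level of each member of 9 cell type marker lists in the library labelled Ad_NC (grey) and in that labelled Ad_AGGF1 (orange), as TMM-normalised CPM plus 0.05 on a log axis; each point is 1 gene and each bar the median of its list. Macrophage genes have the highest median in both libraries (655 CPM in Ad_NC), and activation genes of stellate cells a median of 8.03 CPM in Ad_NC.

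Stellate activation markers and collagens were lower as groups in Ad_AGGF1. Macrophage genes held 4.47% of the reads in Ad_NC, against 0.298% for activation genes. Which cells the activation and collagen reads came from, macrophages included, was not tested. Of the 18 measured activation markers, 5 were at least 2-fold lower, 1 was higher and 12 met neither criterion. Fn1, which encodes the matrix protein fibronectin, was 3.88-fold lower (3.51 to 4.30) with 1889 and 483 reads. Tnc, encoding tenascin C, was 2.20-fold lower (1.94 to 2.50). On fewer reads, Acta2 (96 and 42) was 2.27-fold lower (1.56 to 3.35) and Col1a1 (64 and 22) 2.89-fold lower (1.76 to 4.93). Col3a1 (26 and 12) was 2.15-fold lower (1.05 to 4.68). Spp1, the secreted phosphoprotein osteopontin, was 3.37-fold higher (3.20 to 3.55), with 1918 reads in Ad_NC and 6421 in Ad_AGGF1. Over the 18 members, 12 intervals lay below 0, 1 lay above 0 and 5 held 0. Among the last were Des (18 and 18 reads, log2 ratio 0.01) and Postn (19 and 24 reads, 0.35), both named after their values were seen. The list had a median log2 ratio of −0.71 (−0.85 to −0.48), below all 10000 random lists. Its summed reads differed less, by a log2 ratio of −0.08. In that sum Spp1 offset part of the lower members. The member with the most reads, Vim, named after its values were seen, differed little (10811 and 10633 reads, log2 ratio −0.01).

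Of 13 measured collagens 4 were at least 2-fold lower and none higher, and 10 had an interval wholly below 0. Besides Col1a1 and Col3a1 these were Col6a1, with 27 and 9 reads (2.98-fold, 1.36 to 7.20), and Col6a2, with 30 and 9 reads (3.31-fold, 1.53 to 7.93). The basement membrane chains Col4a1 and Col4a2, chosen after their values were seen, carried most collagen reads, 6233 and 4191 reads for Col4a1 and 4394 and 2638 for Col4a2. Their log2 ratios were −0.56 and −0.73. The median of the collagen list was −0.73 (−0.96 to −0.55), below all 10000 random lists. With the authors' RPKM and a pseudocount of 1 it was −0.55. Other matrix and crosslinking genes had a median of −0.49 (−0.58 to −0.42), again below all random lists. Of its 26 measured members 3 were at least 2-fold lower, among them Loxl4, a lysyl oxidase relative (2.81-fold, 1.42 to 5.97), beside Fn1 and Tnc. Endothelial markers moved with these lists, with a median of −0.69 (−0.77 to −0.58).

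TGF-beta/SMAD target genes and quiescent markers had medians near 0. The 19 measured TGF-beta targets had a median of −0.04 (−0.16 to 0.03) at percentile 29.1 of the random lists, and the list's summed reads a log2 ratio of 0.01 (−0.02 to 0.04). Among them Inhba, the activin A subunit gene, was 2.31-fold higher (2.08 to 2.56), while Nox4, an NADPH oxidase, was 2.04-fold lower (1.37 to 3.07), as were Acta2 and Col1a1. The 16 measured quiescent markers had a median of −0.04 (−0.23 to 0.18) at percentile 33.8, while the log2 ratio of the list's summed reads was 0.40 (0.36 to 0.44). That sum was carried by Plin2, named after its values were seen, with 6305 and 9292 reads, and the reads of the other members had a log2 ratio of −0.0096 (−0.08 to 0.06). Vipr1, a receptor for vasoactive intestinal peptide, was the only member at least 2-fold higher, from 12 and 25 reads (2.10-fold, 1.02 to 4.58), and none was lower. Components of the TGF-beta pathway had a median of −0.15 (percentile 0.20), with Tgfb3 2.98-fold lower (1.03 to 10.5) on 15 and 5 reads. Contractile and actin genes had a median of −0.10 (percentile 6.79), with Acta2 and Tpm2, a tropomyosin (2.32-fold, 1.23 to 4.57), at least 2-fold lower.

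**Figure D2:**
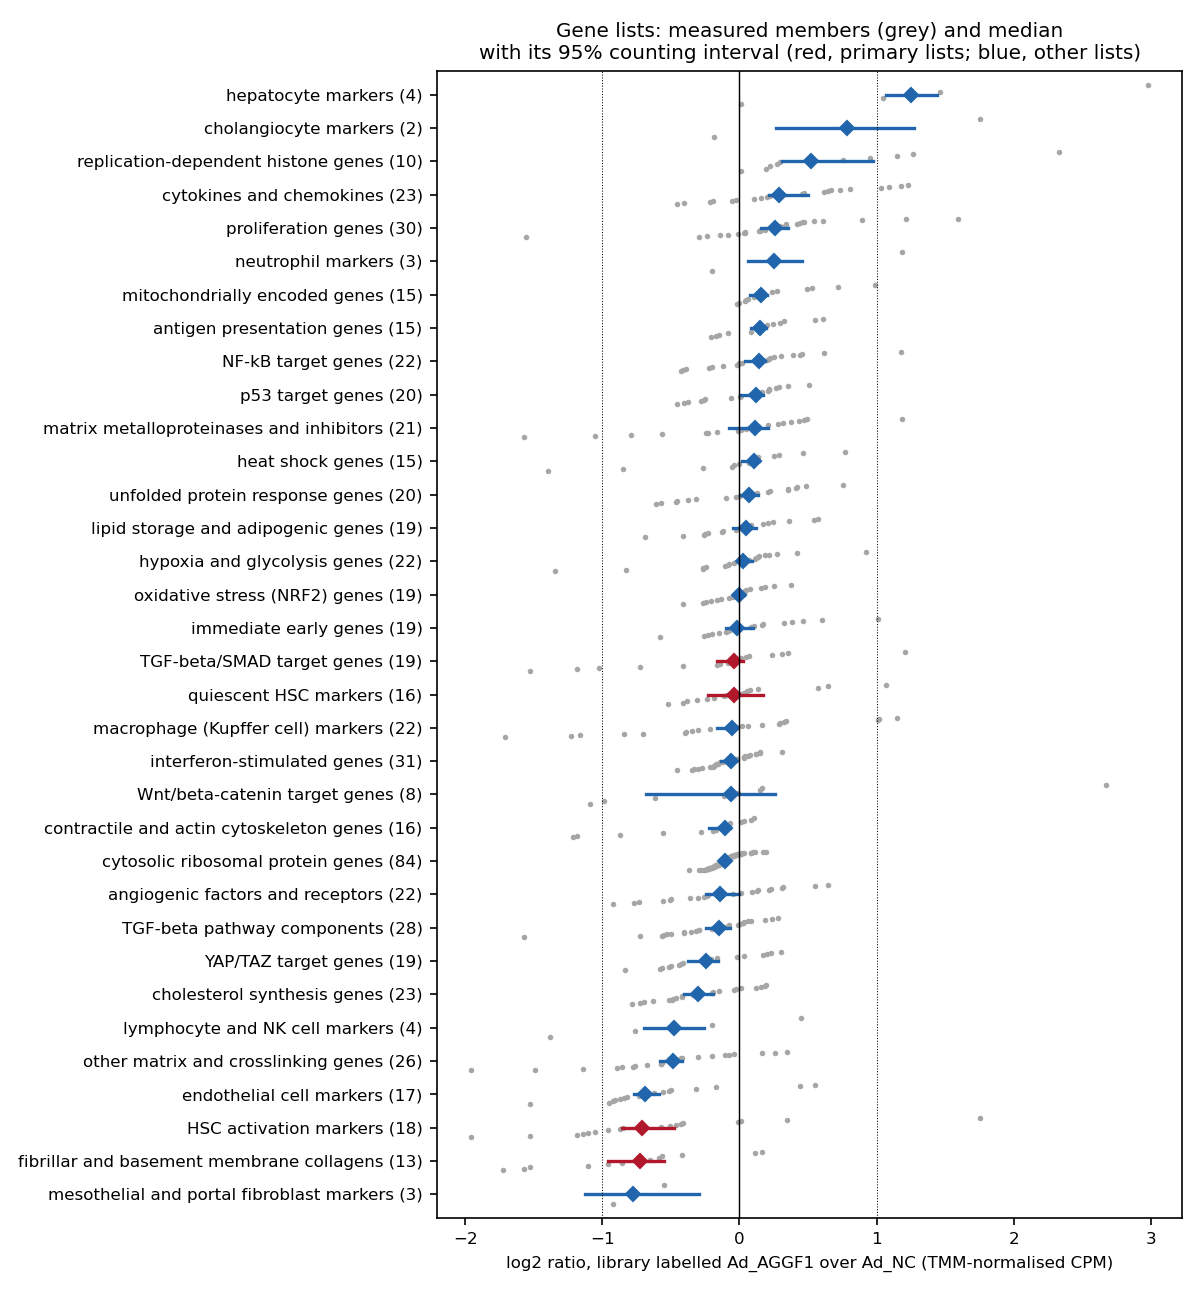
Log2 ratio of the library labelled Ad_AGGF1 over that labelled Ad_NC for each measured member (grey points) of the 34 gene lists, with the median (diamond) and its 95% interval for counting error (bar); primary lists are red, other lists blue, the number of measured members stands in parentheses and dotted lines mark 2-fold. Collagens (−0.73), activation markers (−0.71) and endothelial markers (−0.69) lie to the left of 0, and cytokines and chemokines (0.29) to the right.

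Over all 12120 measured genes, 164 were at least 2-fold higher and 154 at least 2-fold lower in Ad_AGGF1. These are 1.35% and 1.27% of the measured genes, and the median log2 ratio of all measured genes was −0.00078. With at least 100 reads required the counts were 68 and 54, and with the authors' RPKM and a pseudocount of 1 they were 84 and 65.

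Among the higher genes with intervals farthest from 1, the chemokine gene Ccl6 was 2.95-fold higher (2.90 to 3.01), from 14983 to 43960 reads. Cd300lf, an inhibitory myeloid receptor, was 2.86-fold higher (2.50 to 3.28). Pdpn, which encodes podoplanin, was 3.09-fold higher (2.71 to 3.53). Slpi, a protease inhibitor, was 3.20-fold higher (2.49 to 4.15). Arg1, the urea cycle arginase that macrophages also use, was 7.90-fold higher (4.88 to 13.5) with 19 and 149 reads. Further genes in this set were Cyp4f18 (5.15-fold), Ramp3 (5.24-fold), Plxdc2 (3.21-fold), Dlgap2 (5.03-fold) and Pde11a (5.41-fold). Other members rested on few reads in Ad_NC. The mast cell tryptase gene Tpsab1 had 3 and 74 reads, a ratio of 24.8 with an interval of 8.17 to 123. Gstt4 had 2 and 37 reads (4.80 to 160), and Unc93a 2 and 21 reads (2.58 to 93.0).

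The 15 lower genes with intervals farthest from 1 were led by the Fc receptor-like gene Fcrls, with 68 and 3 reads, a 22.5-fold lower ratio with an interval of 7.38 to 112. Slc13a3, a dicarboxylate transporter, was 3.88-fold lower (3.63 to 4.16) with 3993 and 1021 reads. Asb2 was 5.03-fold lower (3.65 to 7.06) and F8, coagulation factor VIII, 4.14-fold lower (3.11 to 5.58). Emcn, the endothelial sialomucin endomucin, was 2.88-fold lower (2.52 to 3.30). Also in this set were Aif1 (3.10-fold), Cd300e (2.97-fold) and Tmem176a (3.18-fold). Ccnd1, which encodes cyclin D1, was 2.94-fold lower (2.35 to 3.71), and Adgrg6 2.74-fold lower (2.28 to 3.31). Fewer reads stood behind Fcrl5 (55 and 8), Cd244a (43 and 9), Hc (27 and 4) and Apob (26 and 3).

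**Figure D3:**
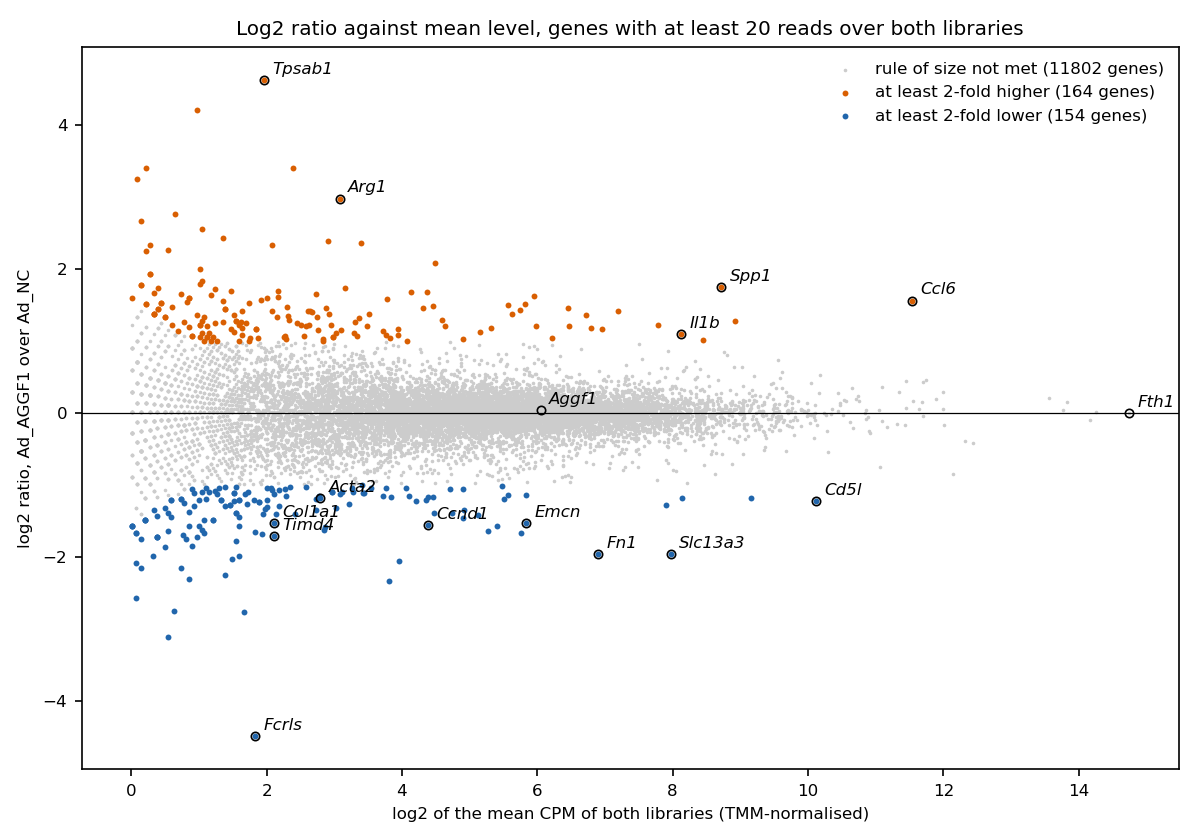
Log2 ratio of the library labelled Ad_AGGF1 over that labelled Ad_NC against the log2 mean CPM of both, for the 12120 measured genes. Orange points are the 164 genes at least 2-fold higher, blue points the 154 at least 2-fold lower and grey points all others. Circles mark some of the genes named in the text. Aggf1 lies at 0.04, and low-count genes show the widest scatter.

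Macrophage markers went both ways. Of the 22 genes, 3 were at least 2-fold lower and 3 higher, and the median was −0.06 (−0.16 to −0.02) at percentile 12.7. Lower were the genes of resident Kupffer cells Cd5l (2.34-fold, 2.28 to 2.41), Timd4 (3.28-fold, 1.96 to 5.71) and Vsig4 (2.23-fold, 1.73 to 2.91). Higher were Clec4f, a Kupffer cell lectin with 10 and 22 reads (2.22-fold, 1.01 to 5.24), and, outside the fixed rule and named after their values were seen, the Fc receptor gene Fcgr3 (2.03-fold) and the scavenger receptor gene Cd163 (2.01-fold). Endothelial markers were lower as a group, below all 10000 random lists. Of 17 measured members 15 had intervals below 0 and 2 above 0, and Emcn alone was at least 2-fold lower.

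Cytokine and chemokine genes were higher as a group, with a median of 0.29 (0.22 to 0.50) above all 10000 random lists. Of the 23 measured, 4 were at least 2-fold higher and none lower. These were the neutrophil chemoattractant Cxcl3 (2.34-fold, 2.20 to 2.50), the cytokines Il6 (2.26-fold, 1.76 to 2.91) and Il1b (2.14-fold, 2.02 to 2.26), and Ccl5 (2.05-fold, 1.72 to 2.44). NF-kB target genes had a median of 0.14 at percentile 99.9, with Il6 the only member at least 2-fold higher. The list's summed reads went the other way, with a log2 ratio of −0.20 (−0.22 to −0.19), but without Saa3, named after its values were seen and holding most of these reads, it was 0.11 (0.09 to 0.13). Interferon-stimulated genes had a median of −0.06 (percentile 7.60) and no member that met the size criterion. Their most abundant members Bst2 and Irf7 had log2 ratios of −0.15 and 0.03. Antigen presentation genes had a median of 0.15 (percentile 98.8) and none that met it, with B2m at 0.20 and H2-D1 at 0.15.

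Among proliferation genes, the median was 0.26 (0.16 to 0.36), at percentile 99.99. Of 30 measured, 2 were at least 2-fold higher, Cenpf on 9 and 27 reads (3.02-fold, 1.38 to 7.30) and Ccne2, cyclin E2 (2.32-fold, 1.55 to 3.53), while Ccnd1 was lower. Replication-dependent histone genes had a median of 0.52 (percentile 99.96) over 10 measured genes, and of 0.29 with at least 100 reads required. Hist2h2be was 2.22-fold higher (1.59 to 3.14), Hist1h2be 2.41-fold (1.36 to 4.43) and Hist1h4j 5.03-fold (1.69 to 20.3), the last on 4 and 20 reads.

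Protease genes had a median of 0.12 (percentile 96.8), with Mmp8, neutrophil collagenase, 2.27-fold higher (2.08 to 2.49) and Plat, tissue plasminogen activator, 2.98-fold lower (1.63 to 5.75). Cholesterol synthesis genes had a median of −0.30 (−0.41 to −0.19), below all 10000 random lists, with no member that met the size criterion. Srebf2, a regulator of this pathway, had a log2 ratio of −0.42, and Insig1 0.19. YAP/TAZ targets had a median of −0.24 (percentile 0.07) with Crim1 at −0.50 and Axl at 0.03, and angiogenic factors and receptors −0.14 (percentile 0.51) with Nrp2 at −0.24 and Hif1a at 0.32. Neither list had a member that met the criterion. The 8 measured Wnt/beta-catenin targets had a median of −0.06 (percentile 37.0), which was −0.99 with at least 100 reads required. All reads of that list summed had a log2 ratio of −0.48 (−0.69 to −0.26), and without Sp5, which had the most reads and was named after its values were seen, −0.30 (−0.55 to −0.04). Ccn4 was 2.13-fold lower (1.53 to 2.99), and Dkk2 was higher on 3 and 19 reads (1.88 to 33.6).

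In the authors' deposited table a p-value is given for 15750 genes, and 30 genes are called, 20 higher and 10 lower. All 30 met the size criterion here and make up 9.43% of the genes that met it. The deposited calls equal a q-value below 0.005 with more than 2-fold change, which selects the same 30 genes. At a q-value below 0.05 the authors' deposited table holds 154 genes, 77 in each direction. The called genes include Fn1, Slc13a3, Cd5l, Emcn and Aif1 on the lower side and Ccl6, Spp1, Il1b, Cxcl3, Inhba, Mmp8 and Ass1 on the higher side. Each q-value in the authors' deposited table comes from 1 library per group and compares those libraries, not the conditions.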

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

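The gene length correction was chosen after seeing the data, and the other settings were planned. The counts of 164 higher and 154 lower genes stayed within 1.5 times under total-count scaling, median-of-ratios factors (163 and 164), no read minimum (220 and 203), no required interval (183 and 174), the authors' RPKM with a pseudocount of 0.1 (155 and 143) or with 1 and no filter (154 and 126), and the length correction (167 and 153). They moved further with at least 100 reads (68 and 54), a 1.5-fold limit (418 and 452), a 4-fold limit (18 and 13) and the authors' RPKM with a pseudocount of 1 (84 and 65). The first 3 of these change which genes can pass, and the last combines the pseudocount of 1 with a filter of a mean of at least 1 RPKM, where changing either choice kept the counts within 1.5 times. The median of collagens under that RPKM setting was −0.55, just outside the counting interval of −0.96 to −0.55, and the log2 ratio of Aggf1 and the medians of the 3 other primary lists stayed inside theirs under each setting run. Of the 64 named genes past the size criterion, 64 kept their direction under total counts, median-of-ratios, RPKM and the length correction, and 43 stayed past 2-fold with RPKM and a pseudocount of 1. The scalings differed little, by 0.0098 on the log2 scale at most. No paired analysis was possible because each group has 1 library, and for the same reason no library could be left out. Depth limits several genes of the primary lists, as Col1a1, Col3a1, Col6a1 and Col6a2 rest on fewer than 100 reads each. With at least 100 reads required, the median of activation markers was −0.52 instead of −0.71. That of collagens was −0.56 instead of −0.73.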

Other observations

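The tests of explanations in this part, the gene length test included, were chosen or revised after their results had been seen. Of the 20 hepatocyte genes 4 were measured, with a median log2 ratio of 1.25, above all 10000 random lists. Those at least 2-fold higher were Arg1, Trf (transferrin, 2.75-fold, 2.19 to 3.48) and Ass1 (argininosuccinate synthase, 2.06-fold, 1.85 to 2.30), while 11 members had no read in either library. Arg1 and Ass1 also serve arginine metabolism in macrophages. Lists with few measured members were cholangiocyte markers (2 measured, Spp1 among them, median 0.79, percentile 97.0, and 1.75 with at least 100 reads), neutrophil markers (3 measured, with Mmp8, median 0.25, percentile 97.4), lymphocyte and NK cell markers (4 measured, median −0.48, percentile 1.87) and mesothelial and portal fibroblast markers (3 measured, median −0.78, percentile 1.30). Cd79b, a B cell receptor component, was 2.61-fold lower (1.44 to 4.97), and Fbln2 and Ly6a had log2 ratios of −0.78 and −0.55.

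The hypoxia and glycolysis list had a median of 0.03 (percentile 73.9), with Ndrg1 2.54-fold lower (2.12 to 3.05), and the heat shock list 0.11 (percentile 94.2), with the small heat shock protein gene Cryab 2.64-fold lower (1.70 to 4.19). No member met the size criterion in the p53 list (0.12, percentile 99.2; Plk2 0.27, Mdm2 0.21), the unfolded protein response (0.07, percentile 93.4; Calr 0.42, Hspa5 0.21) or lipid storage (0.05, percentile 79.9; Cd36 0.36, Lpl 0.17). The same held for NRF2 genes (−0.0050, percentile 46.4; Fth1 −0.0050, Ftl1 0.07), immediate early genes (−0.02, percentile 39.9; Klf6 −0.06, Atf3 −0.09) and mitochondrially encoded genes (0.15, percentile 99.0; mt-Co1 0.04, mt-Nd5 0.12). With the gene length trend removed the mitochondrial median was 0.04, outside its counting interval of 0.08 to 0.20. Cytosolic ribosomal protein genes had a median of −0.11, below all 10000 random lists, with 49 of 84 intervals below 0 and Rpl4 at −0.03 and Rpl13a at −0.14.

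The first pattern weighed was the excess of macrophage over stellate transcripts in libraries labelled as stellate cells. The reads of the activation list were at most 0.0708 of those of the macrophage list. That ratio is not a share of stellate cells. Vim, Lox and Sparc, named after their values were seen, held most activation list reads in Ad_NC (10811, 7613 and 4538 of 29659). Acta2 had 96 reads there and Col1a1 64. A wrong cell type label on 1 library alone is argued against by the shares of macrophage reads, which differed by 1.13-fold between libraries. These shares do not test the virus labels. Cultures made up mostly of macrophages cannot be told apart from other mixtures by the test used here. In each library 17 of 22 macrophage genes lay above the median level of measured genes (27.3 CPM). That share of 0.77 fell short of the 0.8 set for this test after the data were seen. The shortfall therefore does not argue against such cultures. Among the genes below that median were the Kupffer cell genes Clec4f, Timd4 and Vsig4. Lyz2 stood at 18934 and 17744 CPM against 6.42 and 2.22 CPM for Col1a1. By reads, Lyz2 ranked 3 among all genes in both libraries, and Adgre1 ranked 9 in Ad_NC and 10 in Ad_AGGF1. Macrophage transcripts were thus among the most abundant in both libraries, but no cell counts were used here.

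The second pattern was the like level of Aggf1 in both libraries. An insert whose reads were not counted to mouse Aggf1 may explain the level, and so could expression lost by day 8. The upper bound of 0.20 limits only what was counted, the reads were not used here, and these explanations cannot be told apart. Whether the insert was expressed at any time in these cultures was not tested.

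The third pattern was the lower level of collagen and stellate activation transcripts. Gene length bias is argued against, since with the length trend removed the list median nearest to 0 was −0.71, and the trend reached at most 0.03 at these genes against 0.32 over all measured genes. A lower share of stellate cells as the sole cause cannot be told apart from lower expression per cell. Which cells of the cultures, macrophages included, the reads of these genes came from was not tested. Summed reads of 13 stellate identity genes, a set written after the data were seen, were 287 and 260 (log2 ratio −0.13, −0.38 to 0.11). Without Prelp the lower bound was −0.64, which overlaps the interval of the activation list's median. That sets summed reads against a median of gene ratios, which are unlike measures. The summed reads of the activation list had a log2 ratio of −0.08, so this test cannot decide. A lower share of endothelial cells could also lower matrix genes and stays open, as the collagen median lay −0.035 from the endothelial one, and an effect of the virus or a difference between cultures is untested with 1 library per group.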
